A study of Mus musculus with 12 samples.

How the data were processed

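RNA was isolated with a column kit (Qiagen RNeasy Mini), amplified and labelled with biotin, and hybridised to Affymetrix Mouse 430A arrays, 1 array per sample, for 4 quiescent, 4 activated and 4 non-myogenic samples. Per the labels' protocols 5 arrays were labelled with the small-sample kit and 7 with the two-cycle kit, and both kits were used in each group. The deposited values are probe set intensity values on a linear scale, which the submitters' processing notes credit to MAS5, an algorithm that subtracts mismatch from perfect match probes and summarises the probes of a set on each array alone. Its version and settings are not given in the sources used here. The deposited intensity of the arrays lay at different levels, as the 2% trimmed means show, so no scaling to a common level between arrays was visible in them. No detection calls were used, so no background limit could be set for single genes. The largest deposited signal was 19935, and no pair of arrays held identical values.

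Each array was multiplied to bring its mean, trimmed by 2% at each tail, to the common value of 235.14, the median of the 12 arrays' trimmed means. The test had been worded for the deposited values as they stand; scaling was added once these trimmed means had been seen, and before any comparison of groups was run, and the fit on unscaled values was kept as an alternative. Values were turned into log2(signal + 14.696), where the pseudocount is 1/16 of the trimmed mean, so that fold changes are on that scale and understate the change of genes with low signal. Probe sets were named through the platform's annotation table, with symbols checked by Entrez ID for 20364 of the 20380 probe sets with 1 gene. Another 691 probe sets with several genes, 1555 with none listed and 64 controls were left out of the tests. For each of 12393 genes the probe set with the highest mean log2 signal was used, and 7960 genes with a mean signal of at least 47.028, 0.2 of the trimmed mean, were tested. No genome coordinates are given, since the probe set table names no genome build.

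The comparisons were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 12 arrays, with a term for the group and a term for the labelling kit, which leaves 8 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and counts at 2-fold and 5-fold are given beside. Genes that set groups apart had to be called and changed at least 2-fold in both comparisons concerned. Of 43 lists of genes of processes and cell types, holding 949 genes, 40 had at least 5 tested members. They were tested with camera at a preset correlation between genes of 0.01 and an adjustment over the 40 lists, and again with an estimated correlation and with fry. Members of lists in the 3 sets of genes were counted against all 7960 genes tested with a one-sided hypergeometric test, which treats genes as independent. Apart from the scaling and the tests of technical explanations, the groups, comparisons, tests, lists, reference genes and all but 3 alternatives were fixed before the data were examined.

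Genes are named by a rule fixed with the design. Named are 24 reference genes wherever they were tested, which left out Ccnb1 and Ptprc, and per comparison and direction the 8 called genes with the largest fold change among those whose arrays do not overlap. Also named are the 10 genes with the largest smaller fold of each set of genes that set groups apart, and for each list described up to 4 members with the smallest adjusted p and any called member against the direction of most of the list. S100a9, Csf3r and Cxcr2 were named for single arrays after their values were seen.

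The pipeline was tested on simulated data for activated against quiescent cells, with 7960 genes of which 200 were changed. It called 81% of 2-fold and 99% of 4-fold changes, with 8 unchanged genes called, and 0 of 39 unchanged lists. Noise was drawn independently for each gene and the unchanged lists at random, so genes within lists were not correlated. In the data that correlation was estimated at 0.445 for replication and 0.547 for differentiation and sarcomere genes. The 0 unchanged lists therefore say nothing about lists of correlated genes. Only 200 genes were changed, against 5574 called in this comparison in the data. Alternatives were the term for the kit left out, each kit alone, other pseudocounts and signal filters, median centring, quantile normalization, the mean of a gene's probe sets, array weights, a trend with robust variances, only the arrays of the groups compared, a block for the replicate number, and each array left out in turn. Added after seeing the data were the unscaled values, the fit without the 2 small-sample activated arrays, and list medians within each kit with the interaction of kit and group. Overlap between comparisons that share the quiescent arrays was set against 100 simulations of unchanged groups. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.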

Results

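Gene expression was measured in cells sorted from the hind limb muscles of C57BL/6J mice of 8 to 12 weeks, in 3 groups of 4 microarrays each. Quiescent satellite cells, the resident stem cells of skeletal muscle, were collected immediately after sorting with SM/C-2.6, a monoclonal antibody that binds mouse satellite cells, and over 97% of them were Pax7-positive by the labels. Activated satellite cells were the same antibody-positive fraction after 4 days of culture in 20% fetal calf serum with 2.5 ng/ml basic fibroblast growth factor, and over 99% of them were MyoD-positive. Non-myogenic cells bound neither SM/C-2.6 nor an antibody to CD45, the common leukocyte antigen, were collected immediately after sorting, and held under 1% myogenic cells. The labels name no CD45 gate for the antibody-positive fraction. The design sets the quiescent cells against the activated cells and against the non-myogenic cells, to find the genes that mark quiescent satellite cells. Only the activated cells were cultured. Between activated and quiescent cells, activation therefore cannot be told apart from culture or from the time since sorting.

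Of the probe sets with a deposited signal on each array 20380 were assigned to 1 gene, and 7960 genes passed the signal filter. The 2% trimmed mean of the deposited signals ran from 323 to 502 on the 5 arrays labelled with the small-sample kit and from 160 to 236 on the 7 arrays labelled with the two-cycle kit, so every array was scaled to a common trimmed mean of 235 before any comparison. Both kits were used in all 3 groups, with 2 and 2 quiescent arrays, 2 and 2 activated arrays, and 1 and 3 non-myogenic arrays. Across genes, which are not independent replicates, arrays of 1 group correlated at r = 0.903 to 0.989, while quiescent and activated arrays correlated at 0.623 to 0.691 and activated and non-myogenic arrays at 0.442 to 0.523. The 3'/5' signal ratio of the Gapdh control probe sets, which rises with RNA degradation and with the number of amplification rounds, was 4.02 ± 0.969 (SD, n = 4) in quiescent, 3.87 ± 0.916 in non-myogenic and 1.75 ± 0.411 in activated cells. That of the beta-actin probe sets was 2.63 ± 1.04, 1.96 ± 0.374 and 1.62 ± 0.346. The labels do not say whether the 4 arrays of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical, and the number of arrays limits the precision.

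Activated satellite cells had lost much of the transcript of Pax7, the transcription factor that marks satellite cells, and had gained that of Myod1, the transcription factor of committed myoblasts. Pax7 (probe set 1452510_at) fell from a signal of 1071 ± 572 (SD, n = 4) in quiescent cells to 90.2 ± 31.7 in activated cells (log2 fold change -3.29 ± 0.20, SE), while Myod1 (1418420_at) rose from 1277 ± 328 to 4629 ± 1244, a log2 change of 1.85 ± 0.18. The calcitonin receptor gene Calcr (1418688_at) fell from 768 ± 152 to 9.18 ± 7.29, with a log2 change of -5.07 ± 0.22. Genes of DNA replication and mitosis rose together, led by the ubiquitin-conjugating enzyme gene Ube2c of the anaphase-promoting complex pathway (log2 4.63 ± 0.16), and genes of quiescence, immediate early transcription, interferon response and extracellular matrix fell.

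**Figure D1:**
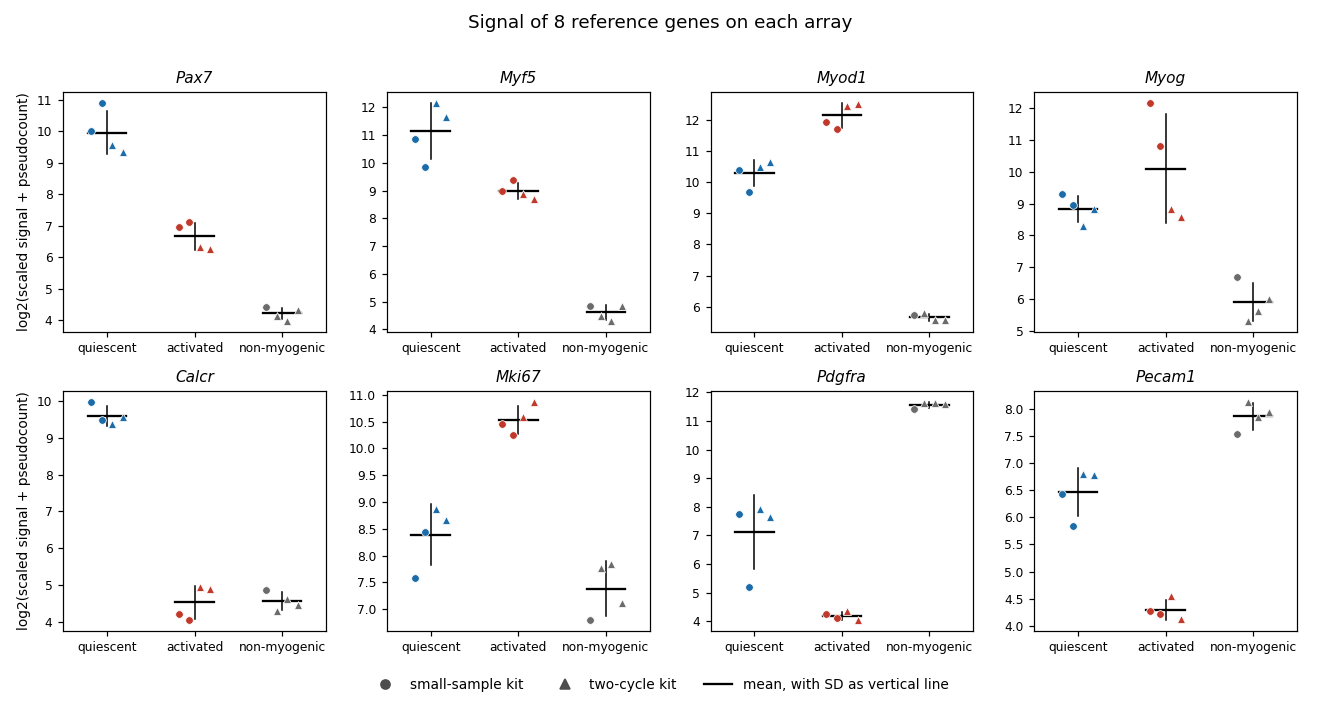
Log2(scaled signal + pseudocount) of 8 reference genes on each of the 12 arrays, by group, where a point is 1 array, its shape the labelling kit, the horizontal line the mean and the vertical line the SD. Pax7 and Calcr were highest in the 4 quiescent arrays, Myod1 and Mki67 in the 4 activated arrays, and Pdgfra and Pecam1 in the 4 non-myogenic arrays.

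Among the reference genes of the myogenic lineage, Myf5, a transcription factor of satellite cells and myoblasts (probe set 1420757_at), fell (log2 -2.16 ± 0.37, -1.17 and -3.15 within the small-sample and two-cycle kits), as did Cdh15, which encodes M-cadherin (-1.08 ± 0.20). Myog, the transcription factor of differentiating myocytes, was higher in activated cells by 1.26 ± 0.40 (adjusted p 0.013), with log2 changes of 2.36 within the small-sample kit and 0.15 within the two-cycle kit (adjusted p 0.608), and 0.76 without activated replicate 1. Its adjusted p was 0.0919 with no term for the kit and 0.0888 with array weights. The intermediate filament gene Des differed by 0.08 ± 0.33 (adjusted p 0.83) at probe set 1426731_at, while its second probe set, 1426732_at, gave a log2 difference of -2.35 and the mean of both -1.13 (adjusted p 0.000371). The skeletal actin gene Acta1 differed by -0.31 ± 0.82 (adjusted p 0.75), and its log2 difference was 2.24 within the small-sample kit (adjusted p 0.000868) and -2.85 within the two-cycle kit (9.14e-06). The surface antigen gene Cd34 fell (log2 -5.45 ± 0.17), as did the adhesion molecule gene Vcam1 (-2.61 ± 0.23), Heyl, a transcriptional target of Notch signalling (-5.12 ± 0.35), and Spry1, an inhibitor of receptor tyrosine kinase signalling (-3.93 ± 0.23).

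The 33 of 34 tested members of the satellite cell quiescence list that fell included Chodl (log2 -7.73), which encodes a lectin-like membrane protein, the bone morphogenetic protein gene Bmp6 (-6.60), Chrdl2 (-5.85), which encodes a chordin-like protein, and Rgs5 (-4.97), a regulator of G protein signalling also abundant in pericytes. The syndecan gene Sdc3, also on that list, rose by 1.67 ± 0.15 at the probe set used, and the mean of its probe sets differed by 0.26 (adjusted p 0.132). The median log2 change of the list was -3.37, -3.12 within the small-sample kit and -3.74 within the two-cycle kit, and the same 33 and 1 members were called when adjusted over the list alone. The list was drawn partly from what the study reported on these samples, so neither count is independent evidence of its direction. Its camera adjusted p was 3.02e-12, and adjusted p = 0.105 with an estimated correlation. All 21 tested endothelial markers also fell, with a median of -2.98 (-2.80 and -3.28 within the kits), among them Fabp4 (-6.71), which encodes a fatty acid binding protein of capillary endothelium and fat cells, the scavenger receptor gene Cd36 (-4.47), Ptprb (-4.40), which encodes the vascular endothelial protein tyrosine phosphatase, and the transcription factor gene Sox17 (-4.01). The reference gene Pecam1, which encodes an endothelial adhesion molecule, fell by 2.17 ± 0.17 on the log2 scale, and the endothelial list had an adjusted p of 2.15e-10, with adjusted p = 0.105 with an estimated correlation. The 3'/5' ratio of Gapdh differed between the same groups, as given above.

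Every tested gene of both cell cycle lists rose. All 29 mitosis genes were higher in activated cells, with a median log2 change of 3.04 (2.94 and 3.19 within the small-sample and two-cycle kits), including the kinesin gene Kif2c (4.05), the polo-like kinase gene Plk1 (3.64) and Hmmr (3.90). As the mean of their probe sets Kif2c rose by 1.80 and Hmmr by 2.365. All 28 genes of DNA replication were higher, with a median of 2.23 (1.83 and 2.55 within the kits), including the thymidine kinase gene Tk1 (4.44), the ribonucleotide reductase gene Rrm2 (4.04), the origin licensing factor gene Cdc6 (3.38) and the primase gene Prim1 (2.50). The reference genes Cdk1, Mki67 and Pcna rose by 4.07 ± 0.21, 2.14 ± 0.21 and 1.24 ± 0.23 (for Pcna 0.68 with adjusted p 0.0582 within the small-sample kit), and Cdkn1c, which encodes the cyclin-dependent kinase inhibitor p57, fell by 3.89 ± 0.23. The camera adjusted p was 8.89e-16 for mitosis and 1.41e-11 for replication, and adjusted p = 0.105 and 0.132 with an estimated correlation.

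Genes of the proteasome, of ribosome biogenesis and of parts of metabolism rose too, while most ribosomal protein genes were lower. All 27 proteasome genes were higher (median log2 1.03, 0.95 and 1.19 within the kits), led by Psmc5 (2.12) and Psmb5 (1.90). Of the 27 genes of ribosome biogenesis 23 were higher and 4 did not pass the test (median 1.17, 0.94 and 1.12), with Wdr12 at 1.96 and Nop2 at 1.60. Of 17 genes of nucleotide and amino acid synthesis 15 were higher (median 1.14, 1.30 and 1.14), led by the asparagine synthetase gene Asns (4.45), the serine synthesis gene Phgdh (3.45) and the mitochondrial folate enzyme gene Mthfd2 (3.03). Of 27 genes of oxidative phosphorylation 24 were higher, 2 did not pass and Cox4i1 was lower (-0.33, adjusted p 0.022), with a median of 0.96 (0.68 and 1.08) and with the ATP synthase genes Atp5g1 (2.19) and Atp5o (1.56) in the lead. The adjusted p of Cox4i1 was 0.0513 or 0.0533 without activated replicate 2 or 3, 0.0577 with a replicate block, and 0.0552 to 0.93 in 7 other settings. Of 16 glycolysis genes 10 were higher and the hexokinase gene Hk1 was lower (-0.80, and -0.61 with adjusted p 0.0635 within the small-sample kit), with a median of 0.92 (0.60 and 0.85). The adjusted p of camera was 1.84e-08, 8.82e-07, 4.03e-06, 6.8e-06 and 0.00969 for these 5 lists in that order, and adjusted p = 0.105, 0.119, 0.105, 0.199 and 0.127 with an estimated correlation. Of 22 ribosomal protein genes 17 were lower, with Rps25 at -0.86 and Rps19 at -0.82, and Rpl27 was higher (0.54, adjusted p 0.047). The adjusted p of Rpl27 was 0.0557 to 0.172 without activated replicate 1, 3 or 4, quiescent replicate 2 or 3 or any non-myogenic array, 0.0566 with a replicate block and 0.0558 to 0.333 in 9 other settings, and its value was 0.34 without quiescent replicate 3. The median of this list was -0.42 (-0.57 and -0.31 within the kits), -0.11 unscaled and -0.06 after quantile normalization. Its camera adjusted p was 0.0142, adjusted p = 0.375 with an estimated correlation, and with the preset one 0.144 unscaled, 0.237 after quantile normalization and 0.152 without the 2 small-sample activated arrays. Of 18 cholesterol synthesis genes 6 were lower and 0 higher (camera adjusted p 0.338), and of 15 fatty acid oxidation genes 4 were higher and 4 lower (0.843).

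The embryonic and fetal muscle genes Tnnt2, Chrng and Myh3 rose, while the differentiation list as a whole differed between the kits. Of 27 tested genes of differentiation and the sarcomere 14 rose, including the embryonic and fetal forms Tnnt2 (log2 5.37 ± 0.22), which encodes cardiac troponin T, Chrng (4.91 ± 0.18), the fetal acetylcholine receptor subunit, and Myh3 (4.77 ± 0.69), the embryonic myosin heavy chain, as well as Chrna1 (2.25 ± 0.23) and Tnnt1 (2.36 ± 0.25). Within the small-sample and two-cycle kits the log2 changes were 5.87 and 4.87 for Tnnt2, 4.92 and 4.90 for Chrng and 6.81 and 2.72 for Myh3. As the mean of its probe sets Chrng rose by 2.41. The creatine kinase gene Ckm, a marker of mature fibres, fell by 3.38 ± 0.48 (-2.10 and -4.66 within the kits). The list's median log2 change was 1.65, but it was 2.49 within the small-sample kit and -0.05 within the two-cycle kit. Its camera adjusted p was 0.00278, adjusted p = 0.426 with an estimated correlation, and adjusted p = 0.469 without the 2 activated arrays of the small-sample kit. Of 21 mature myofibre markers 7 were lower and 2 higher, the enolase gene Eno3 (3.88) and the phosphoglycerate mutase gene Pgam2 (1.96). Pgam2 changed by 0.12 within the two-cycle kit (adjusted p 0.797) and had an adjusted p of 0.0903 with array weights. The median of these markers was -0.97 (0.40 and -2.21 within the kits, camera adjusted p 0.345, and 0.000186 without those 2 arrays).

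Immediate early genes, which are induced within minutes to hours by many stimuli, were high in the freshly sorted cells. The quiescent cells were taken immediately after sorting and the activated cells after 4 days of culture. An effect of isolation or culture on these genes therefore cannot be told apart from activation. All 24 tested members were lower in activated cells, with a median log2 change of -3.77 (-3.33 and -4.35 within the kits), among them the nuclear receptor gene Nr4a1 (-6.91), the cytokine signalling suppressor gene Socs3 (-6.66), Zfp36 (-6.28), which encodes an mRNA decay factor, and the survival gene Mcl1 (-2.85). The reference genes Fos and Egr1 fell (log2 -5.14 ± 0.59 and -3.67 ± 0.35). Fos was measured in activated replicate 1 at 10.49 on the log2 scale, against 7.34 to 7.68 in the others. Interferon response and antigen presentation genes were lower for 24 of 25 members (median -2.20, -2.14 and -2.12 within the kits), with the guanylate-binding protein gene Gbp2 at -3.80 and the immunity-related GTPase gene Iigp1 at -3.52. Camera gave an adjusted p of 2.03e-09 and 4.28e-08, and adjusted p = 0.185 and 0.105 with an estimated correlation. Of 18 Notch signalling genes 14 were lower (median -1.01, camera adjusted p 0.0114, adjusted p = 0.132 with an estimated correlation), including Hey1 (-2.32), while Hes6 (4.22), which encodes an antagonist of Hes1, and the ligand gene Jag2 (1.15) were higher.

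Genes of the extracellular matrix fell as well. Of 27 tested genes of fibrillar collagens and their matrix 21 were lower (median log2 -2.56, -1.73 and -2.98 within the kits), including Col6a1 (-5.68) and the proteoglycan gene Dcn (-5.84), and 3 were higher, Tnc (2.57), Thbs1 (2.47) and Fbln1 (0.81, and 0.52 with adjusted p 0.108 within the small-sample kit). Of 19 fibroblast and fibroadipogenic markers 14 were lower (median -2.0) and Serpinf1 was higher (2.08). The reference genes Col1a1 and Pdgfra, abundant in fibroblasts, fell (log2 -3.65 ± 0.38 and -2.93 ± 0.42), where quiescent replicate 2 had a Pdgfra level of 5.19 on the log2 scale against 7.65 to 7.92 in the others. Camera gave an adjusted p of 0.000614 for the collagen list and 0.00113 for the fibroblast list, and adjusted p = 0.314 and 0.222 with an estimated correlation. In quiescent cells fibroblast markers stood at a median of 8.02% of their non-myogenic signal (0.241% to 113%) and tenocyte markers at 2.53%. By the labels over 97% of the quiescent cells were Pax7-positive. Whether stromal genes fell in satellite cells or with a loss of other cells from the fraction was not tested. The largest decreases over all genes whose groups did not overlap were those of Itih5 (log2 -8.21 ± 0.12), which encodes a hyaluronan-associated protein, Chodl (-7.73 ± 0.22), the apolipoprotein gene Apoe (-7.58 ± 0.24), Dpt (-7.43 ± 0.25), the lipid transporter gene Abca8a (-7.20 ± 0.27), the complement inhibitor gene Serping1 (-7.09 ± 0.23), Nr4a1 (-6.91 ± 0.38) and Prelp (-6.82 ± 0.15). The largest increases were those of the galectin gene Lgals3 (5.88 ± 0.18), the secretin gene Sct (5.67 ± 0.40), Tnnt2, Chrng, Myh3, the metalloprotease inhibitor gene Timp1 (4.65 ± 0.18), Ube2c and Asns.

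In all, 5574 of 7960 genes differed between activated and quiescent cells (limma, Benjamini-Hochberg adjusted p under 0.05), 2532 higher and 3042 lower in activated cells. At least 2-fold changes numbered 1265 and 1716, and at least 5-fold changes 207 and 514. The arrays of the groups did not overlap for 53.4% of the genes, where chance gives 2.86%. Within the kits 4154 genes were called with the 4 small-sample arrays and 5421 with the two-cycle arrays. With the deposited, unscaled values 59.3% of 5217 called genes were higher, against 45.4% here, and the median change of all genes was 0.29 higher on the log2 scale (0.13 higher with quantile normalization, where 51.0% of 5388 were higher). Adjusted over the list alone, 4 cholesterol synthesis genes were lower and 3 fatty acid oxidation genes each higher and lower, and the counts of the other lists described in this comparison equalled those over all genes tested. Camera called 30 of 40 lists, 8 up and 22 down, and none with an estimated correlation, when 15 lists had an unadjusted p under 0.05. Fry, which tests whether the genes of a list move one way, called 38.

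Against the non-myogenic cells, the quiescent satellite cells stood out by genes of the myogenic lineage, and the non-myogenic cells by genes of fibroblasts, tendon and vessels. Myf5 had a signal of 2642 ± 1600 (SD, n = 4) in quiescent and 10.2 ± 4.50 in non-myogenic cells, a log2 difference of 6.60 ± 0.37 (SE), and Pax7 1071 ± 572 and 4.07 ± 2.42, a difference of 5.56 ± 0.20. Pdgfra, the receptor gene of fibroadipogenic progenitors, had 158 ± 92.6 in quiescent and 3023 ± 213 in non-myogenic cells (log2 -4.30 ± 0.42). The tendon gene Chad, which encodes chondroadherin, was lower in quiescent cells (log2 -6.79 ± 0.29).

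All 16 tested genes of the myogenic lineage were higher in quiescent cells, with a median log2 difference of 2.68 (3.20 within the small-sample kit, which held 1 non-myogenic array, and 2.73 within the two-cycle kit). Cdh15 was higher by 5.23 ± 0.21, Myod1 by 4.73 ± 0.19, the acetylcholine receptor gene Chrna1 by 4.65 ± 0.23, Des by 2.37 ± 0.34 and Myog by 2.54 ± 0.41. This list had a camera adjusted p of 1.75e-11 and stayed called with an estimated correlation, with adjusted p = 0.00674. The largest increases over all genes whose groups did not overlap were Myf5, the fibroblast growth factor receptor gene Fgfr4 (6.38 ± 0.39), Chrdl2 (5.61 ± 0.18), Pax7, Asb5 (5.26 ± 0.16), Cdh15, Calcr (5.05 ± 0.23) and the protein kinase C gene Prkcq (5.03 ± 0.24). Fgfr4 was higher by 3.42 as the mean of its probe sets. Vcam1 was higher by 4.24 ± 0.24, Heyl by 3.54 ± 0.35 and Spry1 by 1.13 ± 0.24.

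Of the 34 quiescence genes 19 were higher and 11 lower in quiescent than in non-myogenic cells, with a median of 0.99 (0.63 unscaled), and adjusted over the list alone the counts were 20 and 11. Tenm4, which encodes a teneurin adhesion protein, was higher by 3.98. The 11 that were lower were the endothelial junction genes Cdh5 (-2.32), Esam (-2.42), Cldn5 (-2.24) and Icam2 (-2.14), the collagen genes Col5a1 (-1.48) and Col5a3 (-1.10), and Rgs5 (-1.75), Cd34 (-1.19), Pmp22 (-1.05), Cdkn1c (-0.85) and Sdc3 (-0.61). As the mean of their probe sets Col5a3 differed by -0.52 (adjusted p 0.0556) and Sdc3 by -0.09 (0.633). With no term for the kit the adjusted p was 0.0988 for Col5a3 and 0.181 for Cdkn1c, and that of Cdkn1c was 0.0573 with a replicate block. The list's camera adjusted p was 0.014, and adjusted p = 0.434 with an estimated correlation. This list too is not independent of the study.

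Most genes of ribosomes and mitosis were also higher in quiescent cells, as were 13 of 28 genes of DNA replication. Of 22 ribosomal protein genes 21 were higher (median log2 0.96, 0.90 and 0.98 within the kits), with Rps25 at 2.26 and Rps6 at 2.12, and of 27 genes of ribosome biogenesis 24 were higher (median 1.17, 1.09 and 1.14), with the fibrillarin gene Fbl at 1.80. Of 29 mitosis genes 25 were higher (median 0.84, 0.65 and 0.82), including Bub1b (2.11) and Cks2 (2.02), and adjusted over the list alone 26 were. Of the replication genes 14 did not pass the test, Mcm7 (1.76) and Cdt1 (1.68) were among those higher and Cdc6 was lower (-0.51, adjusted p 0.037), with a median of 0.63 (0.60 and 0.52). The adjusted p of Cdc6 was 0.0671 to 0.205 without quiescent replicate 1 or 3 or non-myogenic replicate 1, 2 or 4, 0.0714 with a replicate block and 0.0519 to 0.174 in 5 other settings. Its value was -0.33 without non-myogenic replicate 1. Mcm7 lay at 10.12 on the log2 scale in quiescent replicate 1, against 10.85 to 10.94 in the other 3. Cdk1 was higher by 1.03 ± 0.21 and Mki67 by 1.16 ± 0.21, while Pcna differed by 0.28 ± 0.24 (adjusted p 0.34, and 0.0303 without quiescent replicate 3). Of 18 cholesterol synthesis genes 12 were higher, with a median of 0.87 (0.83 and 0.89), led by Lss (1.70), which encodes lanosterol synthase. The adjusted p of camera was 7.29e-10, 1.81e-09, 2.96e-07, 0.00115 and 0.000409 for these 5 lists in that order, and adjusted p = 0.107, 0.0913, 0.22, 0.601 and 0.417 with an estimated correlation. With the unscaled values the medians were 0.56 for ribosomal proteins, 0.48 for mitosis, 0.31 for replication and 0.50 for cholesterol synthesis, and that of ribosomal proteins was 0.52 after quantile normalization. Of 24 immediate early genes 12 were higher and Klf2 (-2.56) and Ier5 (-0.78, adjusted p 0.034) lower. The adjusted p of Ier5 was 0.124 or 0.0585 without quiescent replicate 3 or 4 and 0.0609 without non-myogenic replicate 1, and its value was -0.46 without non-myogenic replicate 4. With median centring, array weights, the two-cycle kit alone or no term for the kit, that adjusted p was 0.0687 to 0.225. Fos and Egr1 differed by 0.37 ± 0.60 (adjusted p 0.62) and 0.69 ± 0.35 (adjusted p 0.12). Without activated replicate 1, whose Fos level stood apart, these adjusted p of Fos and Egr1 were 0.0339 and 0.0399, and that of Egr1 was 0.043 without quiescent replicate 2 and 0.0454 with array weights. Within the two-cycle kit they were 0.0121 for Fos and 0.00136 for Egr1, with only the arrays of both groups 0.00925 and 0.00916, and without the 2 small-sample activated arrays 0.00617 and 0.00553. The immediate early list had a median of 0.82 (0.33 and 1.16 within the kits), 0.42 unscaled and 0.52 after quantile normalization, and a camera adjusted p of 0.014, with adjusted p = 0.662 with an estimated correlation and, with the preset correlation, 0.103 after quantile normalization and 0.0513 without quiescent replicate 3.

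Neutrophil genes were raised in the 2 quiescent arrays of the small-sample kit, most in replicate 1. All 5 tested markers were highest in quiescent replicate 1 and second highest in quiescent replicate 2. The signal filter, a mean over the 12 arrays, favours markers that are high on 1 array, so this count was partly fixed by it. Of all 10 measured markers, whatever their signal, 8 were highest in quiescent replicate 1. Ngp, which encodes a granule protein of developing neutrophils, had a signal of 2200 in quiescent replicate 1 and 418 in quiescent replicate 2, against at most 68.4 in the other arrays, and the calprotectin gene S100a8 had 1220, 116 and at most 26.6. Of 5 tested neutrophil markers Ngp (1.83 ± 0.64) and Ltf (1.36 ± 0.44) were called higher than in non-myogenic cells, with a camera adjusted p of 0.206 for the list, and 0.0211 unscaled. The median difference of the 5 was 1.36, but 3.28 within the small-sample kit, which held 1 non-myogenic array, and 0.46 within the two-cycle kit. Without quiescent replicate 1 the Ngp difference was 1.14, and without non-myogenic replicate 1 the adjusted p was 0.168 for Ngp and 0.0589 for Ltf. That of Ngp was 0.0775 within the two-cycle kit, 0.0502 with array weights and 0.0573 with a trend and robust variances, and that of Ltf 0.0528 unscaled.

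**Figure D2:**
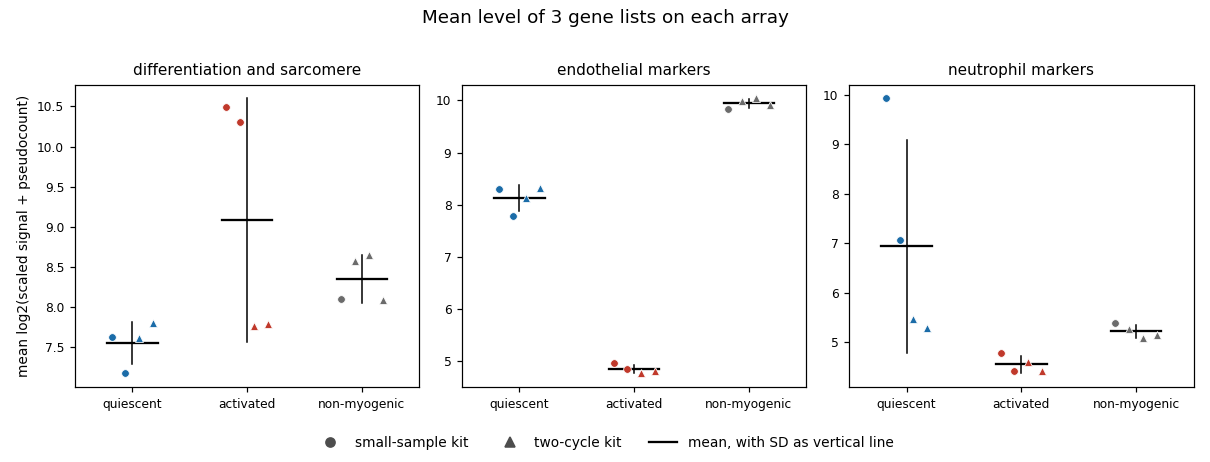
Mean log2(scaled signal + pseudocount) of the differentiation and sarcomere, endothelial and neutrophil lists on each of the 12 arrays, by group, where a point is 1 array, its shape the labelling kit, the horizontal line the mean and the vertical line the SD. The sarcomere mean was higher in the 2 small-sample than in the 2 two-cycle activated arrays, the endothelial mean was lowest in the 4 activated arrays, and the neutrophil mean was highest in the 2 small-sample quiescent arrays, at 9.93 and 7.05, against at most 5.47 in the others.

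The non-myogenic cells carried the stromal genes. All 27 genes of fibrillar collagens and their matrix were lower in quiescent cells (median log2 -2.55, -2.69 and -2.53 within the kits), as were 18 of 19 fibroblast markers (median -3.57, -3.54 and -3.43), including the endosialin gene Cd248 (-6.48 ± 0.25) and the peptidase gene Dpp4 (-6.04 ± 0.13). All 8 tenocyte markers were lower (median -5.09, -5.08 and -4.95), including Chad and the keratocan gene Kera (-5.57 ± 0.18). Of 21 endothelial markers 19 were lower (median -1.94, -1.86 and -1.94), including Kdr (-3.41), the receptor gene of vascular endothelial growth factor. Of 25 interferon and antigen presentation genes 20 were lower (median -1.16, -1.05 and -1.02), including Bst2 (-2.42). The camera adjusted p of these 5 lists was 5.05e-12, 2.58e-10, 1.81e-09, 7.29e-10 and 6.48e-07, and the tenocyte list stayed called with an estimated correlation (adjusted p = 0.0207), whereas the others had adjusted p = 0.132 for collagens and 0.0913 for fibroblast, endothelial and interferon genes. The other largest decreases were Mfap4 (-7.00 ± 0.12), which encodes a microfibril protein, Pi16 (-6.49 ± 0.31), the lipase gene Pla1a (-5.43 ± 0.28) and the dynamin gene Dnm1 (-5.14 ± 0.26). Lower in quiescent cells were also Pecam1 (-1.31 ± 0.18), Col1a1 (-3.57 ± 0.39), Rgs5 (-1.75 ± 0.15) and Acta1 (-2.09 ± 0.84, adjusted p 0.05). The Acta1 adjusted p was 0.0546 to 0.116 without quiescent replicate 1, 2 or 3 or non-myogenic replicate 2, 3 or 4, and 0.0518 to 0.154 in 8 other settings, the highest with a replicate block. On non-myogenic replicate 1, the 1 array of its kit in that group, Kera, Pi16, Pla1a and Rgs5 stood below the other 3 arrays. Of the mature myofibre markers 12 of 21 were lower (median -1.81, camera adjusted p 0.00492, adjusted p = 0.662 with an estimated correlation).

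In this comparison 4214 of 7960 genes differed (limma), 2099 higher and 2115 lower in quiescent cells, with 666 and 1095 changed at least 2-fold and 92 and 312 at least 5-fold. The arrays did not overlap for 39.7% of the genes, where chance gives 2.86%, and 4272 genes were called within the two-cycle kit, whereas the small-sample kit held 1 non-myogenic array. Of the called genes 49.8% were higher in quiescent cells, against 20.7% of 3898 with the deposited, unscaled values, whose median change lay 0.37 lower on the log2 scale, and 60.5% of 4438 with median centring, whose median lay 0.14 higher. With quantile normalization 51.4% of 4321 were higher. Adjusted over the list alone, 15 cholesterol synthesis genes were higher and 1 lower, and 13 mature myofibre markers were lower. As given above, 20 quiescence genes and 26 mitosis genes were then higher, and the other lists described so far kept the counts given. Camera called 20 of 40 lists, 9 up and 11 down, of which 2 stayed called with an estimated correlation.

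Activated cells, which differ from the non-myogenic cells in both lineage and culture, stood above them in most myogenic lineage genes and all mitosis genes, and below them in tendon genes. Myod1 was higher in activated cells by a log2 difference of 6.58 ± 0.19 (SE), from 36.2 ± 3.96 to 4629 ± 1244 (SD, n = 4), and Cdk1 by 5.09 ± 0.21. Fmod, a tendon and matrix proteoglycan gene, fell from 13010 ± 4004 to 2.72 ± 3.18 (log2 -9.33 ± 0.27), and Dpt was lower too (-8.51 ± 0.25). All 29 mitosis genes and all 27 genes of ribosome biogenesis were higher, and all 25 interferon and antigen presentation genes, 21 endothelial markers and 19 fibroblast markers were lower.

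The largest increases also included Chrna1 (log2 6.90 ± 0.23), Ankrd1 (6.46 ± 0.18), which encodes a stretch-responsive muscle ankyrin repeat protein, Sct (5.91 ± 0.41), Tnnt2 (5.56 ± 0.23), Rrm2 (5.17 ± 0.21) and Kif2c (5.02 ± 0.15). Kif2c differed by 2.30 as the mean of its probe sets. The largest decreases also included the tendon genes Thbs4 (-8.46 ± 0.20) and Kera (-7.88 ± 0.18), Dcn (-8.13 ± 0.33), Itih5 (-8.12 ± 0.12), Fabp4 (-7.92 ± 0.24) and Serping1 (-7.79 ± 0.24). Of 16 genes of the myogenic lineage 11 were higher, among them Musk (3.06 ± 0.19), a kinase gene of the neuromuscular junction, Cdh15 (4.15 ± 0.21), Pax7 (2.27 ± 0.20) and Myf5 (4.44 ± 0.37). Pax7 differed by 1.08 with a pseudocount of 1/4 of the trimmed mean. The transcription factor gene Msc (-2.64 ± 0.33, and -1.59 with a pseudocount of 1/4 of the trimmed mean), the dystroglycan gene Dag1 (-1.50 ± 0.30) and Heyl (-1.58 ± 0.35) were lower. The median of the list was 2.16 (2.28 and 2.02 within the small-sample and two-cycle kits). All 8 tenocyte markers were lower (median -7.64, -7.27 and -7.82). The camera adjusted p was 0.000598 for the myogenic and 1.38e-06 for the tenocyte list, and adjusted p = 0.0574 for both with an estimated correlation, so that neither stayed called. Vcam1 was higher by 1.62 ± 0.24. Calcr differed by -0.02 ± 0.23 (adjusted p 0.94, and 0.45 with adjusted p 0.0246 within the two-cycle kit). Myog was higher by 3.79 ± 0.41, and Mki67 and Pcna by 3.31 ± 0.21 and 1.52 ± 0.24. Lower were also Spry1 (-2.80), Cdkn1c (-4.74), Cd34 (-6.64), Fos (-4.77), Egr1 (-2.98), Pecam1 (-3.48), Pdgfra (-7.23), Col1a1 (-7.22) and Rgs5 (-6.72). Des differed by 2.45 ± 0.34 at the probe set used and by 1.13 as the mean of both (adjusted p 0.000416), while the signal of its second probe set, 1426732_at, was 31.3 in activated and 30.5 in non-myogenic cells. Acta1 differed by -2.40 ± 0.84 (adjusted p 0.019), with -4.52 within the two-cycle kit but 0.69 within the small-sample kit, which held 1 non-myogenic array. The pooled Acta1 adjusted p was 0.101 without activated replicate 3 and 0.0973 without activated replicate 4, and 0.0755 with a replicate block and 0.0652 with a trend and robust variances.

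The median log2 difference was 4.03 for mitosis (3.78 and 4.10 within the small-sample and two-cycle kits), 2.13 for ribosome biogenesis (1.86 and 2.27), -3.37 for interferon and antigen presentation genes (-3.03 and -3.51), -4.97 for endothelial markers (-4.70 and -5.29) and -6.29 for fibroblast markers (-6.08 and -6.59). The camera adjusted p was 7.61e-16, 2.63e-11, 4.87e-10, 1.05e-11 and 2.81e-09 in that order, and adjusted p = 0.0574 for the first 4 and 0.0754 for fibroblast markers with an estimated correlation. A total of 5767 genes differed (limma), 2716 higher and 3051 lower in activated cells, 1469 and 1971 of them at least 2-fold and 289 and 850 at least 5-fold, and the arrays did not overlap for 61.6% of the genes (chance 2.86%). Within the two-cycle kit 5785 genes were called. The median change of all genes lay 0.13 higher with quantile normalization and 0.19 higher with median centring, where 52.2% of 5681 and 54.2% of 5787 called genes were higher, against 47.1% here. The counts of the 7 lists described were the same adjusted over the list alone. Camera called 30 of 40 lists, 9 up and 21 down, and none with an estimated correlation, where 17 lists had an unadjusted p under 0.05 and fry called 37.

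**Figure D3:**
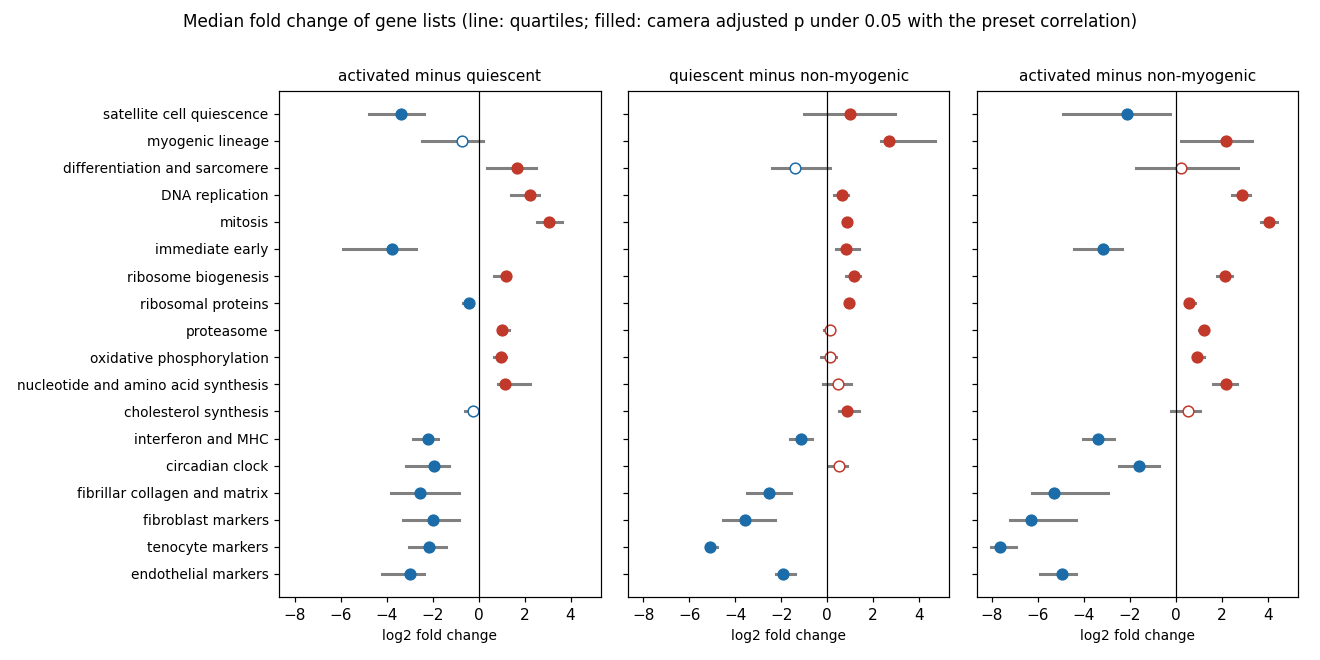
Median log2 fold change of 18 gene lists in the 3 comparisons, with the list on the vertical axis, where the line spans the quartiles of the list's genes and a filled point has a camera adjusted p under 0.05 with the preset correlation. Mitosis genes had medians of 3.04, 0.84 and 4.03, and tenocyte markers of -2.14, -5.09 and -7.64.

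Genes were then sorted by their level in all 3 groups, to find those that set 1 group or lineage apart. The sets can share genes, as Pax7, Cdh15 and Myf5 were both in the quiescent set and in that of both satellite cell groups. At least 2-fold higher in quiescent cells than in both other groups were 311 genes, led by Chrdl2, Calcr, Prkcq, Edn3, which encodes the peptide endothelin 3, and Nap1l5. Edn3 was lower in activated than in quiescent cells (log2 -4.60 ± 0.28) and higher in quiescent than in non-myogenic cells (4.72 ± 0.29). The other 5 leading genes were Tenm4 (log2 3.98 over non-myogenic cells), Blnk (3.83), which encodes an adaptor of B cell receptor signalling, Trib1 (3.69), Otoa (3.69) and Heyl, and Nap1l5 stood 4.05 above. The 311 held 9 of 24 immediate early genes (one-sided hypergeometric test, adjusted p 2.95e-06), 7 of 16 myogenic lineage genes (1.46e-05) and 0 of 21 endothelial markers (adjusted p 1). They also held 16 of the 34 quiescence genes, a count that is not independent evidence, since that list was drawn partly from what the study reported on these samples. The neutrophil genes Ngp and Ltf, highest in quiescent replicate 1, were among the 311 as well. The hypergeometric test treats genes as independent, so its p-values for all 3 sets are too small where the genes of a list are correlated. The correlation between immediate early genes was estimated at 0.525. Camera with it gave this list adjusted p = 0.185 against activated and 0.662 against non-myogenic cells. For these genes quiescence cannot be told apart from an effect of isolation, as given above.

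At least 2-fold higher in activated cells than in both others were 907 genes, led by Sct, Tnnt2, Chrng, Ube2c, Myh3 and Tk1. The next were Hmga2 (log2 4.29 over quiescent cells), which encodes a chromatin protein of proliferating cells, E2f8 (4.28), Hes6 and the desmosome gene Pkp2 (4.08). They held 28 of 29 mitosis genes (adjusted p 2.76e-24), 25 of 28 replication genes (9.08e-20), 16 of 27 ribosome biogenesis genes and 14 of 27 proteasome genes. At least 2-fold higher in both satellite cell groups than in non-myogenic cells were 271 genes, led by Cdh15, Myod1, Chrna1, Asb5, the acetylcholine receptor clustering gene Rapsn and Myf5. Rapsn exceeded non-myogenic cells by 4.44 ± 0.20 in quiescent cells, Ankrd1 by 4.14 ± 0.18, the heparan sulfate sulfotransferase gene Hs6st2 by 4.78 ± 0.27, Lrrn1 by 3.54 ± 0.39 and the galanin gene Gal by 3.51 ± 0.48. They held 17 of 27 ribosome biogenesis genes (adjusted p 1.68e-17) and 11 of 16 myogenic lineage genes (4.38e-12). With a 5-fold threshold the 3 patterns held 49, 143 and 21 genes. Unscaled values gave 172 genes in place of the 311 of quiescent cells and 137 in place of the 271 of both satellite cell groups, for which a pseudocount of 1/4 of the trimmed mean gave 158 and median centring 421. Gal differed between activated and quiescent cells by 1.14 ± 0.47 (adjusted p 0.0421), but by -0.33 within the small-sample kit. Its adjusted p was 0.136 or 0.147 without activated replicate 3 or 4, 0.155 or 0.108 without quiescent replicate 3 or 4, 0.0521 without non-myogenic replicate 2, 0.0786 with a replicate block, and 0.0561 to 0.075 in 5 other settings.

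The term for the labelling kit was associated with 2545 genes, 1007 with higher and 1538 with lower signal in the two-cycle arrays. Of them 293 differed at least 2-fold and none at least 5-fold. Within a group the kits were used on different samples, so this term also holds other differences between those samples. With a replicate block 0 genes were called for the kit (limma, 1057 at an unadjusted p under 0.05), where only 1 replicate number holds both kits. The term for the kit was kept in every comparison above. Against the quiescent cells as a shared reference, 645 genes were higher in both other groups and 956 lower in both, where independent lists of these lengths gave 672.8 and 802.2. Unchanged groups simulated against the same quiescent arrays gave 0. Almost no gene can be called in unchanged groups, so this 0 was fixed in advance and is no reference for the overlap. With the quiescent arrays split between the comparisons, the counts were 462 and 709 or 467 and 679. The correlation of the fold changes across genes was 0.0176 and the covariance 0.0260, where unchanged groups gave 0.488 and 0.0244.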

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

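The tests of the endothelial, sarcomere and neutrophil patterns were chosen, and their criteria revised, only after the values had been seen, while those of other splits of the arrays were planned.

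In the quiescence list the endothelial junction genes Cdh5, Esam, Cldn5 and Icam2, which the endothelial list also holds, were lower in activated than in quiescent cells but highest in non-myogenic cells, where the median quiescent signal was 19.6% of the non-myogenic one. The median log2 difference of quiescent over activated cells was at least 2.74 within each kit, which argues against the labelling kit. Endothelial cells in the sorted fraction would carry all endothelial transcripts. The 4 genes' median log2 ratio of quiescent to non-myogenic cells differed by -0.499 from that of the other 17 markers (SD 0.953, exact two-sided permutation p 0.241), which stood at 27.7% (10.4% to 152%). Pericyte and smooth muscle markers stood at 24.8% (3.44% to 552%) and mature myofibre markers at 29.9% (6.38% to 242%), but fibroblast markers at 8.02% and tenocyte markers at 2.53%. The pericyte list also holds Notch3, Des and Itga7, which are in the sets of genes higher in quiescent or both satellite cell groups. These values therefore do not settle whether the level was particular to endothelial markers. The sort with SM/C-2.6 would remove endothelial cells and left over 97% Pax7-positive cells by the labels. So under 3% of other cells would bring 27.7% only if endothelial cells were under 10.8% of the non-myogenic cells at equal RNA per cell, and neither was measured. So endothelial cells that escaped the sort may be a source, which a CD45 gate would not remove, and with a p above the threshold showing no equality, expression of these genes by satellite cells stays open.

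Sarcomere genes were higher in the small-sample than in the two-cycle activated arrays, with a median log2 difference of 2.66 over the 22 members above the signal filter in quiescent cells. In quiescent cells the same members differed by -0.493 between the kits (quartiles -1.02 and 0.358), which argues against the labelling kit alone. Carried-over muscle fibre RNA is argued against by Ckm, Pvalb and Myh4, which lay at a median log2 of -6.35 relative to the signal that the Acta1 level would bring. The activated minus quiescent difference depended on the kit for 583 of 7960 genes, 433 with higher values in the small-sample and 150 in the two-cycle arrays. Further differentiation of these cultures may be a source, but it cannot be told apart from other differences between the cultures, since the replication and mitosis lists had median log2 interactions of 0.517 and 0.28 with camera adjusted p of 0.000446 and 0.00541 at the preset correlation, and adjusted p = 0.493 for both with an estimated correlation. The mean signal in the small-sample and two-cycle activated arrays was 3150 and 406 for Myog, 2540 and 127 for Myh3 and 1830 and 629 for Tnnt2. These genes are on the sarcomere list itself, so they describe the pattern and are no separate test of that source.

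Neutrophil genes stood out in both small-sample quiescent arrays, with signals of 2200 for Ngp, 1220 for S100a8, 882 for S100a9 and 803 for Camp in replicate 1 and of 418, 116, 82.1 and 50.6 in replicate 2. Of all 10 measured neutrophil markers 8 were highest in replicate 1. Csf3r and Cxcr2 were highest in others, at signals of 51.7 and 13.2, the latter under the pseudocount of 14.696. A criterion asking for every one of the 10 markers would therefore not have been met. Over these 10 replicate 1 exceeded the highest other small-sample array by a median log2 gap of 1.42 (lower quartile 0.182), and the kit left Ngp at no more than 52.5 in the other groups, but since replicate 2 shares the kit, an effect of the labelling kit cannot be told apart from a difference between the cells. Neutrophils in the sorted fraction are a candidate source, which the SM/C-2.6 sort and a CD45 gate would remove, though the labels name no such gate for this fraction. No biological explanation was tested.

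In 42 of 612 groups of 4 values, 1 array stood apart from the other 3, with a gap to the nearest of them as a share of the range, over the 95% critical value of Dixon's test, which chance exceeds in about 1 in 20 groups. Non-myogenic replicate 1 stood below the others for Dpt (0.851), Fbl (0.902), Fmod (0.858), Kera (0.977), Mcm7 (0.898), Pi16 (0.901), Pla1a (0.851), Pmp22 (0.835), Rgs5 (0.965), Spry1 (0.891) and the list of nucleotide and amino acid synthesis (0.878) and above the others for Cdkn1c (0.89), Fzd7 (0.871), the G protein signalling list (0.864) and the deposited trimmed mean (0.844). Non-myogenic replicate 2 stood below the others for Pkp2 (0.933) and above the others for Wdr12 (0.889). Non-myogenic replicate 3 stood below the others for Ngp (0.848). Non-myogenic replicate 4 stood above the others for Egr1 (0.859), the list of matrix proteases (0.848) and the Gapdh 3'/5' ratio (0.843). Quiescent replicate 1 stood below the others for Mcm7 (0.896) and above the others for the Wnt list (0.926). Quiescent replicate 2 stood below the others for Col5a1 (0.852), Pdgfra (0.904), the quiescence list (0.879), the cholesterol synthesis list (0.861) and the autophagy list (0.844) and above the others for Alcam (0.872), Sct (0.881) and Wnt4 (0.838). Quiescent replicate 3 stood above the others for Rps25 (0.888). Quiescent replicate 4 stood above the others for the proteasome list (0.837). Activated replicate 1 stood above the others for Fgfr4 (0.924), Fmod (0.854), Fos (0.891), Heyl (0.876) and the pericyte list (0.896). Activated replicate 2 stood above the others for Itga6 (0.882) and Tnc (0.934). Activated replicate 4 stood below the others for Bub1b (0.934) and above the others for Lgals3 (0.962).

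The bacterial dap transcript, a polyadenylated control added to RNA before labelling, had a mean signal of 2123 in the two-cycle quiescent arrays, 259 in the two-cycle activated and 473 in the two-cycle non-myogenic arrays, and at most 2.4 in the small-sample arrays. The controls phe, lys and thr were also highest in the two-cycle quiescent arrays, by 6.31, 4.0 and 5.19 times over the two-cycle activated arrays. Over the two-cycle non-myogenic arrays they were higher by 3.10, 2.71 and 3.54 times. These quiescent arrays also had the highest beta-actin 3'/5' ratios, 4.09 and 2.57. The cause was not tested, so a technical difference between the groups stays open.

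Of the 35 splits of the 8 arrays of a comparison into 4 and 4, only 1, the real one, called as many genes in each comparison. It called 5574, 4214 and 5767 genes, where the highest other split gave 1, 0 and 0. The real split thus stood apart by its counts as a whole, which does not exclude chance for single genes. The other splits mix groups that differ, which widens the spread within them, so few calls were bound to appear there. Whether the 4 arrays of a group are separate samples is also not given. For the counts of lists chance cannot be excluded, since 3 splits gave at least the 30 lists of activated against quiescent cells (highest other 33), 6 the 20 of quiescent against non-myogenic cells (24) and 5 the 30 of activated against non-myogenic cells (31). Each of these splits kept at least 3 arrays of a real group together, and the 18 splits of each comparison that put 2 and 2 arrays of the groups together gave at most 8, 12 and 26 lists. For genes that set groups apart, 3, 2 and 3 of 100 regroupings, the real one included, gave as many as the 311 of quiescent, 907 of activated and 271 of both satellite cell groups. Other regroupings gave up to 997, 945 and 313. The regroupings that reached these counts kept at least 1 real group together, so their counts reflect the structure of the real groups. Regroupings that mix the groups widen the spread within them, so nothing is concluded about chance from this test. For the labelling kit 1 of 100 exchanges of its labels within groups, the real one, gave the 2545 genes (highest other 928). This sets the arrays of the kits apart, but does not separate the kit from other differences between those samples. A replicate block, which leaves 1 replicate number to separate the kits, gave 0.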

How the results depend on the processing

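The unscaled values, the fit without the 2 small-sample activated arrays and the list medians within kits were chosen only after the data had been seen. The numbers of genes called in the 3 comparisons kept within 1.5 times of those reported under all alternatives run, as did the lists except with an estimated correlation. Of 6288 alternative values of the 229 named gene differences, 6149 kept their call, and their direction where called. Another 122 lost the call, 13 gained it and 4 that were called in either fit reversed direction. Differences called in neither fit count as kept even where the sign changed, as for Fos in quiescent against non-myogenic cells (0.37, and -0.06 with quantile normalization). Values moved by over 1.5 times for 27 of the 229 as the mean of probe sets, 18 with a pseudocount of 1/4 of the trimmed mean, 15 unscaled and 15 with the two-cycle kit alone, and for 12 of 109 with the small-sample kit alone. Of the 27, 21 stayed called in the same direction. Among them, in activated against quiescent cells, were Pkp2 (1.87), Rgs5 (-2.92) and Fabp4 (-4.44). In quiescent against non-myogenic cells Dnm1 (-2.67) and Hs6st2 (2.60) were among them. With each array left out in turn, 5276 to 5555 genes were called for activated against quiescent, 3761 to 4203 for quiescent against non-myogenic and 5390 to 5895 for activated against non-myogenic cells, with 30 to 32, 20 to 23 and 29 to 32 lists. Left-out arrays gave 294 to 329 genes for quiescent, 865 to 939 for activated and 247 to 331 for both satellite cell groups, and 1963 to 2472 for the kit. Camera with an estimated correlation called 0, 2 and 0 lists (15, 10 and 17 at an unadjusted p under 0.05), where fry called 38, 29 and 37. Other thresholds changed the sets of genes by construction, to 49, 143 and 21 at 5-fold and 956, 1973 and 1192 with no fold threshold. Unscaled values gave 172 genes for quiescent cells, 137 for both satellite cell groups and 7527 for the kit, whose arrays then differ in level. For both satellite cell groups a pseudocount of 1/4 of the trimmed mean gave 158, which shrinks the folds of dim genes by construction, and median centring 421, of which the cause was not tested. Acta1 in activated against quiescent cells was at 2.24 with the small-sample kit alone (-0.31 with both), Gal at -0.33 (1.14), Calcr in activated against non-myogenic cells at 0.45 with the two-cycle kit alone (-0.02), and Des in activated against quiescent cells at -1.13 as the mean of its probe sets (0.08), which disagree; the cause was not tested. The call of the ribosomal protein list in activated against quiescent cells (adjusted p 0.0142) was lost unscaled (0.144), with quantile normalization (0.237) and without the 2 small-sample activated arrays (0.152). In quiescent against non-myogenic cells the heat shock list (0.0251) was lost with median centring (0.0518) and quantile normalization (0.103). Of 12 same-number pairs of arrays, 9 had correlated deviations over 0.1 (-0.374 to 0.392), among them all 4 of quiescent and activated arrays (0.146 to 0.279). These share the kit, pairs of the same kit and other numbers had 0.212 to 0.31, and within group and kit same-number pairs had -0.0887 to -0.0285, as a test chosen only after the data had been seen showed, so the numbers were not taken to pair the samples. A replicate block gave 5302, 3344 and 5325 genes, 32, 20 and 31 lists, 310, 911 and 269 genes setting groups apart, and 0 kit genes with limma (1057 at an unadjusted p under 0.05, 2545 without the block), since 1 number alone holds both kits. Signal over background was not available per probe set, so differences of dim genes are limited by the pseudocount.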

Other observations

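Of the values in this part, the list medians within each kit and the unscaled values were chosen only after the data had been seen. Genes of lipid handling, metals and the clock also differed between activated and quiescent cells. Of 14 genes of the circadian clock 13 were lower in activated cells (median log2 -1.94, -1.90 and -2.0 within the small-sample and two-cycle kits), led by the repressor genes Bhlhe40 (-4.75 ± 0.40) and Per1 (-4.14 ± 0.25) and the nuclear receptor gene Rora (-4.02 ± 0.21). Of 19 lipid transport genes 12 were lower (median -1.89), with Apoe at -7.58, while the fatty acid binding protein genes Fabp7 (3.04 ± 0.21) and Fabp5 (2.10 ± 0.15) were higher. Of 20 genes of iron and copper handling 13 were lower (median -0.93, -0.62 unscaled), with the ceruloplasmin gene Cp at -6.21 ± 0.17 and the metalloreductase gene Steap4 at -4.63 ± 0.25, and 3 were higher, Steap1 (3.44 ± 0.20), the transferrin receptor gene Tfrc (2.51 ± 0.21) and the heme oxygenase gene Hmox1 (2.42 ± 0.39). The camera adjusted p of these 3 lists was 8.93e-05, 0.00649 and 0.0389, and adjusted p = 0.163, 0.301 and 0.127 with an estimated correlation. Of 27 adhesion and junction genes 16 were lower and 7 higher, the latter led by N-cadherin Cdh2 (3.71 ± 0.24), Alcam (2.46 ± 0.31), the integrin gene Itga6 (2.11 ± 0.14) and Cdh11 (2.10 ± 0.26), besides Jam2 (1.57), Gja1 (0.79) and Itgb1 (0.74). Gja1 differed by 0.49 (adjusted p 0.15) within the small-sample kit. Itgb1 differed by 0.24 (adjusted p 0.302) within the two-cycle kit and had an adjusted p of 0.184 without the 2 small-sample activated arrays. The adhesion list as a whole did not pass (camera adjusted p 0.0533), but was at 0.0193 to 0.0464 with the other scalings, 0.0469 without non-myogenic replicate 1 and 0.0415 without quiescent replicate 2. The counts of these 4 lists were the same adjusted over the list alone. The endothelial markers fell with these groups, as given in the report.

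Most genes of Wnt signalling were lower in both satellite cell groups than in non-myogenic cells. Of 18 tested genes 11 were lower in quiescent than in non-myogenic cells (median log2 -1.04, -1.34 and -1.01 within the kits, the small-sample kit holding 1 non-myogenic array), among them the secreted inhibitor genes Wif1 (-4.67 ± 0.22), Sfrp2 (-4.53 ± 0.20) and Sfrp4 (-3.97 ± 0.18) and the receptor gene Fzd2 (-2.69 ± 0.16), while the ligand gene Wnt4 was higher (2.60 ± 0.25). In activated cells 16 of the 18 were lower than in non-myogenic cells (median -1.94, -1.85 and -2.04), led by Sfrp4 (-5.87 ± 0.18) and Wif1 (-5.32 ± 0.22). The camera adjusted p was 0.000255 for quiescent and 3.05e-05 for activated against non-myogenic cells, and adjusted p = 0.0913 and 0.0574 with an estimated correlation. Between activated and quiescent cells 12 were lower, with Wnt4 at -3.56 ± 0.24, and Fzd2 (2.11 ± 0.15) and Fzd7 (0.42 ± 0.17, adjusted p 0.045) were higher. Fzd7 had an adjusted p of 0.0532 to 0.15 without any 1 array except quiescent or activated replicate 4, 0.0915 with a replicate block and 0.05 to 0.528 in 8 other settings, and its value was 0.15 within the two-cycle kit. The median of the list in this comparison was -0.76 (-0.62 and -0.98), and it did not pass (camera adjusted p 0.0527), but was at 0.0316 to 0.0498 unscaled, with median centring, with a replicate block, and without activated replicate 2, quiescent replicate 2, non-myogenic replicate 3 or the 2 small-sample activated arrays. The counts of this list were the same adjusted over the list alone. Of 19 genes of the heat shock response 10 were higher in quiescent cells, 11 when adjusted over the list alone, led by Dnajb1 (2.02 ± 0.22) and Hsph1 (1.58 ± 0.21), and 3 were lower, Hspb8 (-3.19 ± 0.27), Hmox1 (-1.41) and Trib3 (-0.63). Hmox1 had an adjusted p of 0.0596 without non-myogenic replicate 1 and 0.33 with no term for the kit. The median of the list was 0.70, 0.30 unscaled and 0.38 after quantile normalization. Its camera adjusted p was 0.0251, adjusted p = 0.269 with an estimated correlation, and with the preset one 0.103 after quantile normalization and 0.0518 with median centring. Fibroblast and tenocyte markers were lower in the same comparison, as given in the report.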
